A study of Arabidopsis thaliana with 12 samples.

How the data were processed

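Total RNA of 6 WT and 6 psak samples of Arabidopsis thaliana, ecotype Columbia 0, was measured on arrays of 3439 probes. The values used were the intensities the authors deposited, 1 per probe and sample, on a linear scale from 0 to 100 with the brightest probe at or just under 100. How the authors scanned, background-corrected and scaled these intensities is not given in the sources used here, so it is not known what an intensity of 0 stood for before scaling. Probes at the top of the scale may be compressed by its ceiling, and probes near 0 carry large errors on a log scale. In all, 2358 probes were above 0 in every sample and 138 were at 0 in every sample. The deposited log2 medians of the values above 0 ran from -2.20 in psak 6 to -1.25 in psak 2.

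Genes were named through the platform's probe table, with symbols updated through the RefSeq annotation of TAIR10.1. Of the probes, 692 list 1 gene, 870 list several and 1877 are not listed and are unnamed here. Only probes with 1 gene are named, and 690 of these matched a locus of the annotation. No coordinates are given, because no genome build is named for the array. The names are those of the probe table and were not checked against probe sequences.

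Values of 0 were treated as missing, the others were taken to log2, and samples were quantile normalized because neither sums (within 1%) nor log2 medians (within 0.1) were equal. Probes with at least 2 values in each group were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, psak minus WT, Benjamini-Hochberg adjustment), which left 2993 probes and 446 untested ones. Because of the normalization and of the zeros left out, log2 fold changes can differ from the ratio of the deposited means printed beside them. Gene lists of at least 3 tested members were tested with cameraPR at a preset correlation of 0.01 on the moderated statistics. The camera test with an estimated correlation and fry were run on probes above 0 in all samples. Adjustment was over 13 lists.

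The labels number the samples 1 to 6 in each genotype and do not say whether they came from separate plants or cultures. P-values then measure only the spread between these samples, part of which may be technical. Samples 1 and 2, 3 and 4, and 5 and 6 were mostly nearest to each other: the SD of their log2 difference was 0.634 to 0.966 in WT, against 0.853 to 1.08 for other WT samples, and 0.700 to 0.902 in psak, against 0.827 to 1.23. The rule fixed before the data were examined, which would have averaged pairs with an SD under 50% of the other pairs' median, was not met, and all 6 samples per group entered as replicates.

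The named genes follow a rule fixed before the data were examined: PSAK, the 12 highest and 12 lowest log2 fold changes among probes past the threshold, and up to 4 members of each list with the smallest p. Because most of these probes have no single gene, the same rule was also applied to single-gene probes alone, a choice made after the data were seen. The 12 lists taken from names on the array were drawn up after those names were seen and before any fold change was computed.

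The fit was tested on simulated data with 2993 probes, of which 200 were changed by 1 or 2 on the log2 scale, with the spread of the real probes. With independent samples, 51.0% and 83.0% of the changed probes were recovered, and 2 of 136 calls were false. With noise shared within number pairs at a correlation of 0.590, 73 of 224 calls were false in the fit of 12 samples. With number pairs as a random block 5 of 124 were false, and with pair means 4 of 84. Here and below, a random block held the 2 samples of 1 number pair in 1 genotype, so WT and psak shared no block. Every simulated probe had the same correlation, which is what the random-block fit assumes. Its false calls where correlations differ between probes were not tested. The shared noise was also drawn separately for each probe. False calls where many probes share the same noise were therefore not tested for any of these fits. Alternatives included other normalizations, an offset before log2, a filter on dim probes, blocks and means of sample numbers, each sample left out, trend and robust variances and an exact permutation test per probe. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.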

Results

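RNA of Arabidopsis thaliana was hybridised to an array of 3439 probes, with 6 wild-type samples (WT, ecotype Columbia 0) and 6 samples of the psak mutant in the same ecotype. The mutant lacks PSI-K, a membrane subunit of photosystem I that helps to bind the light-harvesting antenna. The comparison asks which transcripts differ between plants with and without this subunit. Deposited intensities ran from 0 to 100. Between 13% and 19.4% of the probes of a sample stood at exactly 0, and the sum of intensities per sample was 2967 to 3460. The number of samples, 6 per genotype, limits the precision of every value.

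PSAN, which encodes the lumenal photosystem I subunit that takes part in the docking of plastocyanin, was higher in psak. Its deposited intensity was 2.97 ± 0.841 (SD, n = 6) in WT and 6.85 ± 2.07 in psak, a log2 fold change of 1.43 ± 0.25 (SE; limma adjusted p = 0.00366). LHB1B2 (LHCB1.5), which encodes a major antenna protein of photosystem II, stood at 12.1 ± 3.52 in WT and 31.1 ± 8.08 in psak, a log2 fold change of 0.997 ± 0.19 (limma adjusted p = 0.00497). CCL, a transcript under circadian control, fell from 9.54 ± 1.24 to 3.69 ± 0.790, a log2 fold change of -1.31 ± 0.13 (limma adjusted p = 0.000257). For each of these 3 genes all 6 psak samples lay beyond all 6 WT samples. Such a separation held for 279 of 2358 probes above 0 in all samples, against 236 expected if the samples of each number pair moved as 1. All 3 genes passed with number pairs as a random block (limma adjusted p = 0.0142, 0.0238 and 0.00239). None passed with pair means (limma adjusted p = 0.187, 0.209 and 0.151). Within sample numbers 1-2, 3-4 and 5-6, the log2 fold changes were 1.66, 1.18 and 1.46 for PSAN, 0.89, 0.90 and 1.2 for LHB1B2, and -0.98, -1.39 and -1.55 for CCL. For 2 further thylakoid proteins the transcript was lower in the test of 12 samples, but not with sample numbers as a random block (adjusted p = 0.135 and 0.107 with limma). NdhS, a subunit of the chloroplast NADH dehydrogenase-like complex, had a log2 fold change of -0.52 ± 0.15, and AT1G76450, a PsbP-domain protein, one of -0.82 ± 0.25 (limma adjusted p = 0.0364 and 0.0455).

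**Figure D1:**
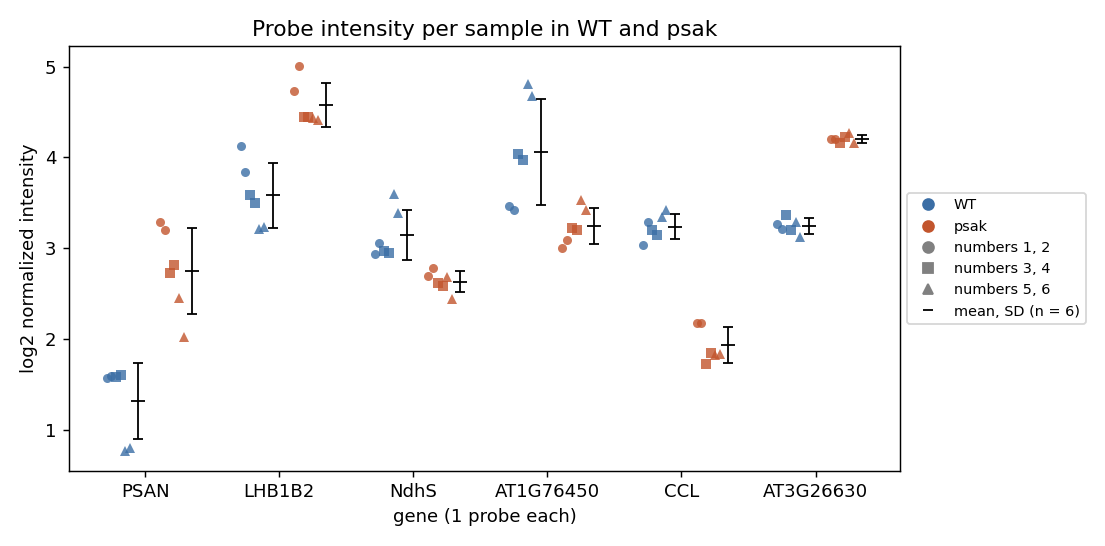
Log2 normalized intensity (vertical axis) of the probes listed for 6 genes in the 6 WT and 6 psak samples, with marker shapes for sample numbers 1 and 2, 3 and 4, and 5 and 6, and bars for the mean and SD of each group. PSAN lay between 0.76 and 1.60 in WT and between 2.02 and 3.29 in psak, and samples with neighbouring numbers mostly lay close together.

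Over the array, 243 probes were higher and 201 lower in psak at an adjusted p under 0.05 among 2993 tested, and 138 and 77 of them differed by more than 2-fold. Among the 595 tested probes that name a single gene, 34 were higher and 46 lower. With the values as deposited and no further normalization, the split was 146 higher and 275 lower, and the median log2 fold change of all probes was -0.11. Of the 444 called probes, 421 had a value in each of sample numbers 1 and 2, 3 and 4, and 5 and 6, and 417 of these had the same direction in all 3. In the brightest 25% of the probes this was so for 232 of 233 such calls and in the dimmest 25% for 38 of 39, where another 18 calls lacked a value in a number pair. Called probes are picked for a difference that holds over the samples, which favours 1 direction. Over all 2758 probes with a value in each number pair, 42.7% had 1 direction in all 3, against 25% if signs were independent and equally likely. In 32.1%, numbers 5-6 were opposed to the others.

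Among single-gene probes past the threshold, the largest increases were those of DRT101 (log2 fold change 3.15 ± 0.72, limma adjusted p = 0.0142), AT4G18540 (2.35 ± 0.71, 0.0461) and AT4G05070 (2.09 ± 0.48, 0.0120). Their WT intensities were 0.150 ± 0.133, 0.0546 ± 0.0321 and 0.323 ± 0.266. DRT101 and AT4G18540 each had 1 psak sample at 0, which the log2 test leaves out. With an offset that keeps zeros, their log2 fold changes were 1.68 and 1.18, and neither passed (limma adjusted p = 0.204 and 0.215). AT4G18540, the only one of the 3 in the dimmest 25% of the probes, was also lower in psak by 0.84 on the log2 scale within numbers 5 and 6. Brighter probes followed. PRA1.B6, a prenylated Rab acceptor of the endomembrane system, rose from 3.61 ± 1.63 to 9.0 ± 3.63, and AT1G32730 rose from 1.17 ± 0.282 to 2.57 ± 0.402. AT3G06570 rose from 2.80 ± 0.628 to 5.67 ± 0.926. AT3G47650, which encodes a chloroplast protein with the zinc-finger domain of DnaJ chaperones, rose from 0.841 ± 0.139 to 1.67 ± 0.347. The log2 fold changes of these 4 genes were 1.53, 1.46, 1.28 and 1.27, with limma adjusted p of 0.0159, 0.00137, 0.000592 and 0.00184. AT2G39100, AT5G19900, AT1G51080 and AT1G27660 completed the 12, with log2 fold changes of 1.38, 1.36, 1.33 and 1.23 on probes with WT intensities of 0.0702 or less. AT1G27660 had 2 psak samples at 0, and with the offset its log2 fold change was 0.05 (limma adjusted p = 0.999).

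The lowest log2 fold change of a single-gene probe past the threshold was that of AT2G03140 (-3.43 ± 0.87, limma adjusted p = 0.0400), a dim probe above 0 in 4 WT and 3 psak samples. DI21, a drought-inducible gene, fell from 0.551 ± 0.0936 to 0.185 ± 0.0543, a log2 fold change of -1.65 ± 0.36 (limma adjusted p = 0.0105). APS4, a plastid ATP sulfurylase, which activates sulfate for assimilation, fell from 0.555 ± 0.0922 to 0.256 ± 0.0979, and CSLA01, a glycosyltransferase of the cellulose synthase-like family, had a log2 fold change of -1.21 ± 0.29. Bright probes that fell were AT2G46220, from 11.7 ± 2.85 to 5.16 ± 1.38, and AT1G51350, from 5.30 ± 0.335 to 2.17 ± 0.163. Their log2 fold changes were -1.17 ± 0.26 and -1.07 ± 0.13 (limma adjusted p = 0.0109 and 0.000471). AT2G46300 fell from 2.90 ± 1.16 to 1.16 ± 0.353. AT2G18920, AT3G50880, AT4G39230 and AT2G37880 had log2 fold changes of -1.56, -1.46, -1.26 and -1.11. CSLA01 and AT3G50880 each had 1 WT sample at 0. With the offset, AT2G03140, AT4G39230, CSLA01 and AT3G50880 had log2 fold changes of -0.98, -1.03, -0.48 and -0.67 and did not pass (limma adjusted p = 0.114, 0.0700, 0.483 and 0.561). Without regard to names, 2 of the 12 highest and 2 of the 12 lowest called probes had a single gene, and 11 of the 12 highest were in the dimmest 25%. Unnamed probe 3499 was above 98 in all 6 psak samples (99.8 ± 0.441) and at 37.5 ± 14.4 in WT. If values at the top of the scale were cut off, its intensities give only a lower bound of the difference. The highest value of any probe in psak 3 was 98.9, short of 100.

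The 20 gene lists drawn up before the data were examined had 12 tested members in 7 lists. The single tested member of the photosystem I list, PSAN, and that of the photosystem II antenna list, LHB1B2, rose over all genes. None of the other 10 tested members passed over all genes. In the photosystem II list, PSBW had a log2 fold change of -0.51 and PSBY one of 0.38 (adjusted p = 0.107 and 0.209 with limma), and PSBW passed adjusted over the list alone. The chlorophyll synthesis list held CHLM, the magnesium protoporphyrin methyltransferase, at 0.63 and AT1G74470, geranylgeranyl reductase, at -0.16 (limma adjusted p = 0.0576 and 0.551), of which CHLM passed adjusted over the list alone. The probe listed for PRK, the phosphoribulokinase of the Calvin cycle, whose listed name is in doubt, stood at -0.04 (limma adjusted p = 0.939). AT3G52960, a peroxiredoxin, stood at 1.33 (limma adjusted p = 0.0867). As the only tested member of its list, its p adjusted over the list alone is its unadjusted p of 0.0175. Of 4 nuclear genes of plastid ribosomal proteins, 3 had values below 0 and AT1G29070 stood at 2.95 and passed adjusted over the list alone. Its probe was at 0 in 3 WT and 3 psak samples, and with the offset the log2 fold change was 0.58 (limma adjusted p = 0.532). The members of the fixed lists that passed over the list alone but not over all genes, PSBW, CHLM, AT3G52960 and AT1G29070, had limma adjusted p of 0.223, 0.346, 0.386 and 0.205 over all genes with the random block. The PSBW value within numbers 5-6 was 0.17, opposite to the others. The ribosomal list, the only fixed one with at least 3 tested members, had a median of -0.16, a mean of 0.56 and an upward camera statistic (adjusted p = 0.964, and 0.982 with an estimated correlation).

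Another 12 lists were taken from the names on the array before any fold change was computed, and none passed camera either (adjusted p = 0.964 for each, and 0.982 for each with an estimated correlation). In the list of photosystem, NDH and thylakoid electron transfer proteins, 2 of 9 tested members rose (PSAN and LHB1B2), 2 fell (NdhS and AT1G76450) and 5 did not pass. The fry test for a shared direction gave an adjusted p of 0.186 for this list and 0.922 for both the pentatricopeptide repeat and the mTERF list. Its test for change in either direction gave these 3 lists 0.00230, 2.4e-07 and 0.00909, but it takes the 12 samples as independent and does not compare a list with other genes. Of all tested probes, 29.2% were at an unadjusted p under 0.05. Among 17 pentatricopeptide repeat genes, a family of organelle RNA-binding proteins, the probe listed for AT3G26630, a name that is in doubt and was not checked against its sequence, rose from 9.78 ± 1.44 to 21.7 ± 3.14 and AT4G21170 fell from 1.42 ± 0.308 to 0.716 ± 0.0815. Their log2 fold changes were 0.96 ± 0.11 and -0.77 ± 0.16 (limma adjusted p = 0.000288 and 0.00721). Of 6 mTERF genes, which act in organelle gene expression, AT5G55580 (mTERF9) rose by 0.86 on the log2 scale and AT1G62150 fell by 0.83. Of 7 factors for the assembly and expression of thylakoid complexes, AT1G22700, a tetratricopeptide protein of photosystem I assembly, fell by 0.66 (limma adjusted p = 0.0358). NTRC, the chloroplast thioredoxin reductase, fell by 0.64 and was the only one of 6 redox genes to pass (limma adjusted p = 0.00836). The sucrose phosphate synthase ATSPS4F rose by 0.53 (limma adjusted p = 0.0111; 0.29 with the values as deposited, where it did not pass), and the other 3 carbon metabolism genes did not pass. APS4 was the only one of 9 genes of amino acid, nucleotide, cofactor and lipid synthesis to pass. No member passed among 5 plastid ribosomal protein genes of an extended list, 5 tetrapyrrole and carotenoid genes, 4 fibrillins, 3 histone H3 genes and 5 regulators of reproductive and meristem tissue. The extended ribosomal list (median -0.18, mean 0.30), the redox list (-0.11, 0.02) and the fibrillins (-0.05, 0.04) also had medians and means of opposite sign, with camera statistics that pointed down, down and up.

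**Figure D2:**
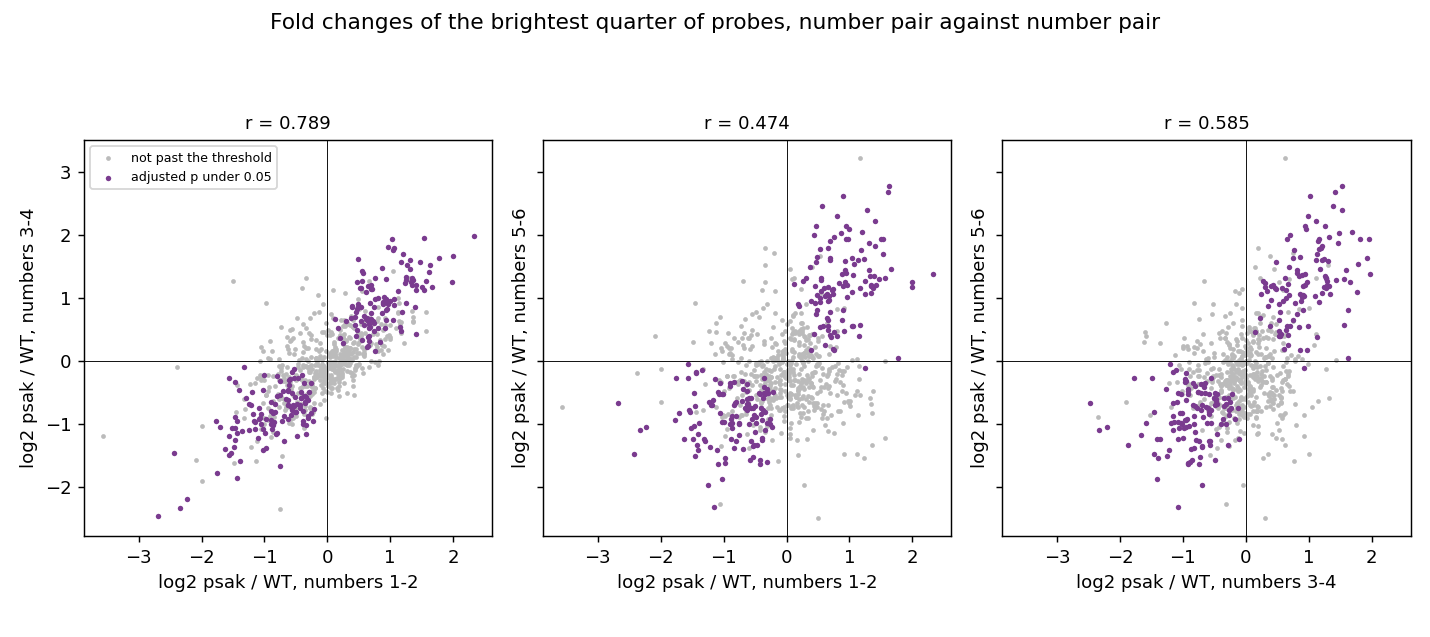
Log2 fold change of psak over WT in each pair of sample numbers (1-2, 3-4 and 5-6) against that in another pair, for the brightest 25% of the probes, with probes at an adjusted p under 0.05 in purple. Pearson's r across probes, which are not independent replicates, was 0.789, 0.474 and 0.585 from left to right. Over all probes it was 0.467, 0.052 and 0.151.

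Samples with neighbouring numbers were alike, and the test above treats all 12 as independent. The SEs printed with the log2 fold changes come from that test, so they make no allowance for noise shared within number pairs. With numbers 1 and 2, 3 and 4, and 5 and 6 within each genotype as a random block (consensus correlation 0.590), limma called 99 probes higher and 55 lower. Of the genes named here, these included PSAN, LHB1B2, CCL, AT3G26630, PRA1.B6, AT1G32730, AT3G06570, AT3G47650, AT5G19900 and AT1G51350. Of 54 named probes past the threshold 36 did not pass with this block, among them DRT101, DI21, APS4, NTRC, AT5G55580, AT1G62150, AT1G22700, AT4G21170, AT2G46220 and ATSPS4F. Of the other largest increases, AT4G18540, AT4G05070, AT2G39100, AT1G51080 and AT1G27660 did not pass with it either. Nor did AT2G03140, AT2G18920, AT3G50880, AT4G39230, CSLA01, AT2G37880 and AT2G46300 among the decreases. With the mean of each pair as 1 replicate (n = 3 per group), limma called 0 probes, with 465 of 2965 at an unadjusted p under 0.05. The 9 other ways to split these means into 3 and 3 mix the genotypes. They had 39 to 361 probes at an unadjusted p under 0.05 with limma. The psak samples 5 and 6 had the most probes at 0 (18.1% and 19.4%), and without them 524 probes were higher and 423 lower. PSAK itself was not analysed here, because no probe carried its name alone, so the genotype labels were not checked by its level. With the values as deposited, AT1G76450, NTRC, CSLA01, AT5G19900, AT2G18920, AT4G18540, AT2G39100, AT5G55580 and ATSPS4F kept their direction without passing (limma adjusted p from 0.0536 to 0.223). LHB1B2 belongs to a family of near-identical genes, and its probe was not tested for specificity among them.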

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

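The tests on psak samples 5 and 6 and on the signs of the 3 number pairs were chosen after the results were seen; those on splits of the samples were written before. Outliers were sought in 159 groups of 6 values, from named probes and from sample measures (share of probes at 0, summed intensity and log2 median). In 12 groups, all of named probes, 1 sample lay far from the other 5. Its gap to the nearest, divided by the whole range, was above Dixon's critical value. Chance flags about 1 in 20 groups of 6 independent and normally distributed values. Samples of a number pair were alike, so the rate by chance here is not known. In WT these were AT4G18540 (ratio 0.717, sample 2), unnamed probe 4099 (0.669, sample 3), APS4 (0.663, sample 2), AT3G54210 (0.720, sample 5), AT1G31790 (0.684, sample 1), AT5G55580 (0.788, sample 2) and AT1G51110 (0.633, sample 4). In psak these were unnamed probe 2522 (0.640, sample 5), AT3G50880 (0.650, sample 1), AT5G58330 (0.634, sample 5), SRX (0.627, sample 5) and AT1G31220 (0.648, sample 5), so that 4 of 5 flags in psak fell on sample 5. Outside the tested probes, AT2G25830 was above 0 in 5 of 6 psak samples (mean 0.135 ± 0.227) and AT4G35980 in 5 of 6 (0.108 ± 0.123), against 0 of 6 WT samples each. Fisher's exact test gave an unadjusted p of 0.0152 for each and an adjusted p of 1. Over 3439 probes, even the smallest p of this test for 6 against 6 samples passes only if many probes reach it.

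The 444 calls of the 12 samples fell to 0 with pair means. Of 100 drawn splits of the 12 samples into 6 and 6, only the real one called as many probes (1 of 100), and the highest other called 2. This would speak against chance only if the samples were independent, which the consensus correlation of 0.590 goes against. Nearly all the other drawn splits break up number pairs, so they cannot test noise shared within them. Splits that keep the number pairs whole number 10, too few for a share under 0.05. The random-block fit was not run on them. In the fit of 12 samples, the highest of the 9 others called 167. The real count exceeded this by more than the 1.5 times set in advance as the bound against shared noise, but the bound was too weak, since the real split leads 10 such splits by chance 1 time in 10; noise shared within number pairs therefore stays open as a part or the whole of the calls, and the consensus correlation of 0.590 shows that such noise is present. In the brightest 25% of the probes, 57.4% had 1 sign in all 3 number pairs, against at most 21.8% for any pattern with 1 pair opposed. If signs were independent and equally likely, 25% would be expected. The share met the prediction for a genotype difference present in all 3 pairs, whose bound was set after the results were seen. Probes are not independent of each other, and the share was not computed for other splits. It therefore cannot tell a genotype difference from noise shared within number pairs. Over all probes the share was 42.7%, with numbers 5-6 opposed in 32.1%, and between the dimmest and the brightest 25% the lead over that pattern was small or nil (38.8% against 37.4%, and 37.0% against 37.0%). Whether plants of each genotype were also grown or handled apart was not tested.

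The psak samples 5 and 6 stood apart from the other psak samples, with 18.1% and 19.4% of probes at 0 against 13% to 13.6%. The split that called 167 probes put them on 1 side with WT samples 1, 2, 5 and 6. A swap of WT and psak within numbers 5 and 6 would turn the sign of their fold changes, but in the brightest 25% these correlated with those of the other number pairs at no less than 0.474, which argues against it. A loss of signal near the floor in these samples stays open: in the dimmest 50% of the probes the 5-6 fold changes correlated with the mean of the others at 0.00568, against 0.555 in the brightest 25%. The correlation of numbers 1-2 with 3-4 fell as well, from 0.789 to 0.357, so that the fall for 5-6 was larger by only 0.118, too little to decide.

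Of the 12 highest calls, 11 were in the dimmest 25% of the probes. Of the 57 calls in that part of the array, 18 lacked a value in a number pair, 38 had 1 direction in all 3 pairs and 1 was opposed in a pair.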

How the results depend on the processing

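The settings that leave out number pairs or psak samples 5 and 6, or use number pairs as a block, were chosen after the data were seen. Against 243 probes higher and 201 lower, counts stayed within 1.5 times in both directions with an offset, without the dimmest 25%, with means of numbers 1+4, 2+5 and 3+6, with trend and robust variances and with the exact permutation test per probe. None of these settings allows for noise shared within number pairs, so their counts do not bear on it. The means of 1+4, 2+5 and 3+6 put neighbouring numbers into different replicates, and the permutation test exchanges all 12 samples freely. Leaving out each sample in turn gave 180 to 305 higher and 147 to 278 lower. The values as deposited gave 146 higher and 275 lower, equal sums 146 and 263, and equal log2 medians 141 higher and 125 lower. Number pairs within each genotype as a random block gave 99 and 55. Pair means gave 0 and 0 with limma (465 of 2965 at an unadjusted p under 0.05). Other splits that keep the number pairs whole had 39 to 361 such probes. With the number pair as a block too, pair means gave 0 and 0 (463). The number pair as a fixed block over 12 samples, shared by WT and psak, gave 309 higher and 348 lower. Without psak samples 5 and 6 the counts were 524 and 423, without numbers 5-6 in both groups 441 and 334, without 1-2 126 and 76, and without 3-4 52 and 39. The cause was not tested in any of these cases, except that fewer samples entered the last ones. Same-numbered WT and psak samples deviated from their group means with correlations of 0.075 to 0.213, of which 4 of 6 were over 0.1, short of the rule that every one be so, and the numbers were not used to pair samples. Still, 5 of 6 WT and 5 of 6 psak samples correlated best with their own number, and summed intensities of psak over WT were 0.982, 1.01 and 0.994 within numbers 1-2, 3-4 and 5-6, hints from the data and not from the design that the numbers share something. The replicate block gave 212 higher and 220 lower. The plastid ribosomal list did not pass under any alternative, with medians of -0.30 to -0.08 when a sample was left out and 0.10 without numbers 5-6. Of 54 named probes past the threshold, 18 stayed past it with the random block, 0 of 53 with pair means, and none changed sign. Among the rest of the 92 named probes, 45 values changed sign across the alternatives, none of them past the threshold before or after. The alternatives for the level of PSAK were not run, for want of a probe with its name alone. Dim probes limit all of this: no background measure was used here, and signal over background is unknown.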

Other observations

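The genes of this paragraph were chosen after their values were seen, because their probes stayed past the threshold with number pairs as a random block. With that block, 14 single-gene probes were higher and 4 lower among 595. Beyond the genes of the report, CYN, which encodes cyanase, the enzyme that breaks down cyanate, rose by 1.17 on the log2 scale (limma adjusted p = 0.0126 with the block). AT5G11650 rose by 1.1, AT5G03370 by 1.07, AT5G19210 by 1.04, AT5G38360 by 0.94 and AT5G59400 by 0.82. AT4G32060 fell by 0.92 and AT3G04650 fell by 0.86.

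The brightest 25% of the probes held 114 of the 243 higher and 120 of the 201 lower calls. Among 2358 probes above 0 in all samples, the 6 WT and 6 psak values did not overlap at all for 279, where chance would give 5.10 with 12 independent samples and 236 if the samples of each number pair moved as 1. Unnamed probe 2266 was above 0 in all 6 WT samples (0.307 ± 0.156) and at 0 in all 6 psak samples, the only probe of 3439 with this pattern, and no probe had the opposite one. Unnamed probe 4588 was above 0 in 6 WT samples and 1 psak sample. Fisher's exact test gave unadjusted p of 0.00216 and 0.0152 for these probes and an adjusted p of 1 for both. The first is the smallest p this test can give for 6 against 6 samples, so 1 such probe among 3439 could not pass.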
